A study of Ovis aries with 96 samples.

How the data were processed

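Rumen fluid of 16 sheep was profiled by sequencing of the 16S rRNA gene, in 96 libraries: 8 sheep per diet (hay or grain), each sampled at 6 clock times. Per the labels' protocols, DNA was extracted with the TIANamp Stool DNA Kit and amplicons were sequenced on an Illumina NovaSeq instrument as paired ends of 250 bases. The deposited table holds counts per sequence feature and library, with the taxonomy of each feature, and the authors' only tool named in the submitters' processing notes is R 4.2. The primers, the tool that made the features from reads, its filters and the taxonomy database are not given in the sources used here. The values are whole numbers with no scaling between libraries, as tested on the table. The lowest total of a feature over all libraries is 250 and the lowest count above 0 in a library is 2, so rare features were removed before the table was deposited. A value of 0 therefore means that a feature is listed at 0, and no detection limit can be derived from it; richness values are lower than those of an unfiltered table. Of 946 features, 99 carry no genus name (5.36% of counts) and were summed as unclassified members of the next rank. All columns of samples were used.

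Counts were summed per genus. Sheep was the unit of replication. For the diet comparison, the 6 libraries of a sheep were summed, and edgeR 4.0.16 (R 4.3.3) was run with TMM factors, filterByExpr (minimum count 10, minimum total 15), a robust quasi-likelihood fit and Benjamini-Hochberg adjustment at 0.05, for 71 genera and for 254 features. For single clock times the same test was run on 8 against 8 libraries. For time, libraries of 1 diet were fitted with the sheep as a block, testing 5 time coefficients together, or the cosine and sine of a 24 h period. The interaction of diet and time was tested in the same way over 104 genera. Adjusted p-values of genera and features in the report are from edgeR unless another tool is named. Log2 fold changes are grain minus hay, with approximate standard errors. These are the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Relative abundances are percent of a library's counts, averaged over the 6 libraries of a sheep, and given as mean ± SD of 8 sheep.

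Shares of phyla with at least 0.1% in a diet (12) and of 14 lists of genera were compared between diets by exact permutation of the 16 sheep (12870 splits, two-sided, smallest p 0.000155) with Benjamini-Hochberg adjustment within each family. Changes over time were tested by the F statistic with times permuted within sheep (100000 draws for 1 value, 9999 for distances). Shannon diversity and the number of features were computed after thinning each library to 33286 counts, the lowest total, averaged over 20 draws. Because rare features are missing from the table, this thinning removed hardly any feature. Genus composition was compared by a permutational partition of the variance of Bray-Curtis distances (R²), between sheep means for diet and between libraries for time. Community tests were run in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. Counting error is small at these totals; the number of sheep limits the precision, and intervals would cover counting error only, since reads are not independent molecules.

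The lists, the designs and the alternatives were fixed before the data were examined. The lists are fibre degraders, uncultured groups of fibre diets, starch and sugar users, lactate producers, lactate users, succinate and propionate formers, pectin and treponeme group, methanogens, sulfate reducers and acetogens, wall-attached taxa, mouth and airway taxa, hindgut and faecal taxa, reagent and environment taxa, and plant organelle 16S. Genera are named in the text by a rule fixed at the same time. Between diets these are the 12 largest rises and the 12 largest falls among named genera past the threshold, with at least 0.1% in a diet and the same direction at all 6 times. To these come the 5 most abundant genera of each diet, up to 4 members of each list, and the 8 genera with the smallest p in each diet's 24 h fit and in the interaction, with at least 0.1%. For features the 3 most abundant called ones in each direction are described, and for phyla all with at least 1% in a diet.

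Alternatives were DESeq2 1.42.0 with poscounts size factors, scaling by library totals, TMMwsp, limma 3.58.1 on centred log-ratios (pseudocount 0.5), limma-voom on libraries, other filters, other distances and ranks, each clock time and each sheep left out in turn, and the sheep number as a block. Added after the data were seen were joining sheep 1 and 5, 2 and 6, 3 and 7, and 4 and 8 of a diet into 4 units, leaving out 6 libraries that were nearest to another sheep, leaving out sheep 4 and 8 of both diets, the place in the numbering shared by sheep 1 and 5, and so on, of both diets as a block, the phylum time courses, the number of features over time, thinning to 1000 counts, the counts without Prevotella, and each named genus with each sheep left out in turn.

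The tests were tried on simulated counts with the means, spread and totals of the real sheep. For the diet comparison of 71 genera, 7 of 12 genera changed 16-fold (58.3%) and 1 of 12 changed 4-fold (8.33%) were recovered. Of 47 unchanged genera 0 were called. For the 254 features, 24 of 100 changed 16-fold (24%) were recovered, and 0 of 54 unchanged ones were called. For the 24 h cosine over 75 genera, 10 of 10 changes of 16-fold (100%) were recovered on hay. On grain, where sheep vary more, 4 of 10 (40%) were recovered. The recoveries of genera rest on sets of 10 or 12, so they are rough. Changes of 4-fold were often missed in these sets, above all on grain. Of unchanged genera, 1 of 55 was called by the cosine on grain, and 1 of 84 by each test of the interaction. In simulations without a difference, the exact test gave p under 0.05 in 3.25% of cases and the permutation within sheep in 4%. Error control for sheep that resemble each other in pairs was not tested.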

Results

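Rumen fluid was taken through a rumen fistula from 16 sheep, and the 16S rRNA gene, a marker by which bacteria and archaea are named, was sequenced from it. Of these sheep, 8 ate a hay-based diet and 8 a grain-based diet with 40% forage and 60% concentrate, in a trial of 30 days. Feed was given at 8 h, and each sheep was sampled at 6 clock times (2, 6, 10, 14, 18 and 22 h) of 1 day, called T2 to T22 below. This gave 96 libraries in 12 groups of diet and time with 8 libraries each. Total counts per library ran from 33286 (hay sheep 8 at T2; the next lowest was 44142) to 65673, with a median of 54327.5. The median was 58385 in grain and 52054.5 in hay libraries. The table lists 946 sequence features, which fall into 120 genus entries, 107 of them named, and 16 phyla. A library held 38 to 228 features in grain-fed and 135 to 258 in hay-fed sheep. Archaea made up 1.18% of all counts.

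Libraries of 1 sheep resembled each other more than libraries of different sheep. The median correlation of log relative abundances was 0.839 within a sheep and 0.690 between sheep of the grain diet, 0.925 and 0.835 in the hay diet, and 0.454 between diets. Within each diet, sheep 1 and 5, 2 and 6, 3 and 7, and 4 and 8 resembled each other: their mean Bray-Curtis distance over features was 0.405 against 0.796 for other grain-fed sheep, and 0.290 against 0.535 in hay-fed sheep. The labels name no such pairs. The place in the numbering below means the set of 1 such pair in each diet, such as sheep 1 and 5 of both. The 8 sheep of a diet are therefore not shown to be 8 independent units. Where joining these pairs into 4 units per diet ends the call given for a genus, a phylum or a list between diets, or for a genus over the day, the joined value is given. Calls of features, of single times and of phyla over the day were not tested one by one with joined pairs.

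The question of the diet comparison is how the rumen community differs between hay and grain feeding. The community of hay-fed sheep was a Bacteroidota community led by Prevotella, a genus of starch, sugar and protein users. On grain, Firmicutes took the lead, Prevotella fell, and Bifidobacterium, Olsenella and Streptococcus, genera with lactate-forming species, appeared next to more Methanobrevibacter, a methane-forming archaeon. Bacteroidota made up 24.4% ± 12.0 of counts in grain-fed and 71.9% ± 4.32 in hay-fed sheep (mean of sheep means ± SD, n = 8 per diet), and all 8 grain-fed sheep lay below every hay-fed sheep (exact permutation test, two-sided, adjusted p = 0.000466). Firmicutes made up 56.8% ± 21.2 against 24.7% ± 4.91, with 6 of 8 grain-fed sheep above every hay-fed sheep (exact permutation, adjusted p = 0.00396). Actinobacteriota stood at 13.5% ± 23.2 in grain-fed sheep and at 0.00927% ± 0.0262 in hay-fed sheep, where 1 of 8 sheep held any (exact permutation, adjusted p = 0.000466). The size of this difference rested on sheep 4 and 8: it was 13.5 percentage points over all sheep, 6.93 without grain sheep 8 and 1.26 without sheep 4 and 8 of both diets. The call was lost when any 1 hay-fed sheep was left out (exact permutation, adjusted p from 0.197 to 0.215), although the difference stayed at 13.5 percentage points and all 8 grain-fed sheep above every hay-fed sheep. Of the 1267 splits that then reached the real difference, 1266 put grain sheep 4 and 8 together into the smaller group of 7, where they weigh more. The archaeal phylum Euryarchaeota rose to 2.07% ± 1.42 from 0.242% ± 0.132 (exact permutation, adjusted p = 0.00218). Chloroflexi rose to 1.62% ± 1.35 from 0.0177% ± 0.0138 (exact permutation, adjusted p = 0.000466). Patescibacteria rose to 1.08% ± 1.05 from 0.0875% ± 0.0339 (exact permutation, adjusted p = 0.0158). Of the 12 phyla tested, 11 passed 0.05, the exception being Cyanobacteria (exact permutation, adjusted p = 0.107; 0.0393 to 0.0475 without hay sheep 1, 7 or 8). With the sheep pairs joined, 7 phyla passed, and Firmicutes and Spirochaetota (exact permutation, adjusted p = 0.103 for each) and Patescibacteria and Synergistota (0.114 for each) were lost. Without sheep 4 and 8, Spirochaetota (exact permutation, adjusted p = 0.0779) and Synergistota (0.171) were lost, and Patescibacteria without the 6 libraries that resembled another sheep (0.0744). On centred log-ratios, which do not rest on shares, the fall of Bacteroidota had an adjusted p of 0.0532 and the rise of Patescibacteria 0.0699 (exact permutation).

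The 2 diets separated in the genus composition as a whole. Diet accounted for 45.3% of the variance of Bray-Curtis distances between the 16 sheep (permutational partition of distances, exact permutation p = 0.000155, the smallest that 8 against 8 sheep can give). Grain-fed sheep also differed more among themselves: the mean distance of a sheep to the others of its diet was 0.555 ± 0.101 on grain and 0.211 ± 0.0242 on hay. Within a sheep, the mean distance between its 6 libraries of the day was 0.356 ± 0.0849 on grain and 0.175 ± 0.0542 on hay (exact permutation p = 0.000155). Every grain-fed sheep lay above every hay-fed sheep, but narrowly: the lowest on grain was 0.263 and the highest on hay 0.246. This was not computed without the 6 libraries that resembled another sheep. Among these, grain sheep 4 at T22 lay 0.985 over features from its own nearest library, and 0.449 from grain sheep 5 at T22.

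Among 71 genera tested between diets with edgeR, 46 passed an adjusted p of 0.05, 19 higher and 27 lower in grain-fed sheep. This split depends on the low-count filter. Of the 49 genera that the filter left untested, 27 were listed at 0 in all hay-fed and 9 in all grain-fed sheep. Without the filter, more genera were called higher than lower on grain. Christensenellaceae R-7 group rose to 11.5% ± 8.80 from 3.58% ± 1.26 (log2 fold change 1.72 ± 0.58 SE, adjusted p = 0.0138), with 6 of 8 grain-fed sheep above every hay-fed sheep and 1 below all of them. Clostridia UCG-014 rose to 9.38% ± 13.4 from 0.496% ± 0.177 (log2 fold change 4.61 ± 0.80, adjusted p = 8.22e-05), a mean that grain sheep 7 with 40.3% pulls up (4.96% without it). NK4A214 group, of the Oscillospiraceae, rose to 8.94% ± 6.17 from 1.00% ± 0.494 (log2 fold change 3.20 ± 0.56, adjusted p = 8.22e-05). Ruminococcus, with cellulose- and starch-degrading species, rose to 3.54% ± 2.77 from 0.972% ± 0.887 (log2 fold change 2.13 ± 0.78, adjusted p = 0.0221). Lachnospiraceae NK3A20 group rose by 3.43 ± 0.81 log2 units, and Candidatus Saccharimonas, a small bacterium that lives on other bacteria, by 3.77 ± 0.90 (adjusted p = 0.00117 for each). Candidatus Saccharimonas makes up all of Patescibacteria, so its rise is not a second result beside that of the phylum. By permutation, the call of the phylum was lost under the alternatives given above. With the sheep pairs joined, the rises of Christensenellaceae R-7 group (adjusted p = 0.0694) and Ruminococcus (0.0781) were no longer past the threshold. A value given for joined sheep pairs in a diet comparison is the highest adjusted p over the alternatives of that genus, unless a range is given.

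**Figure D1:**
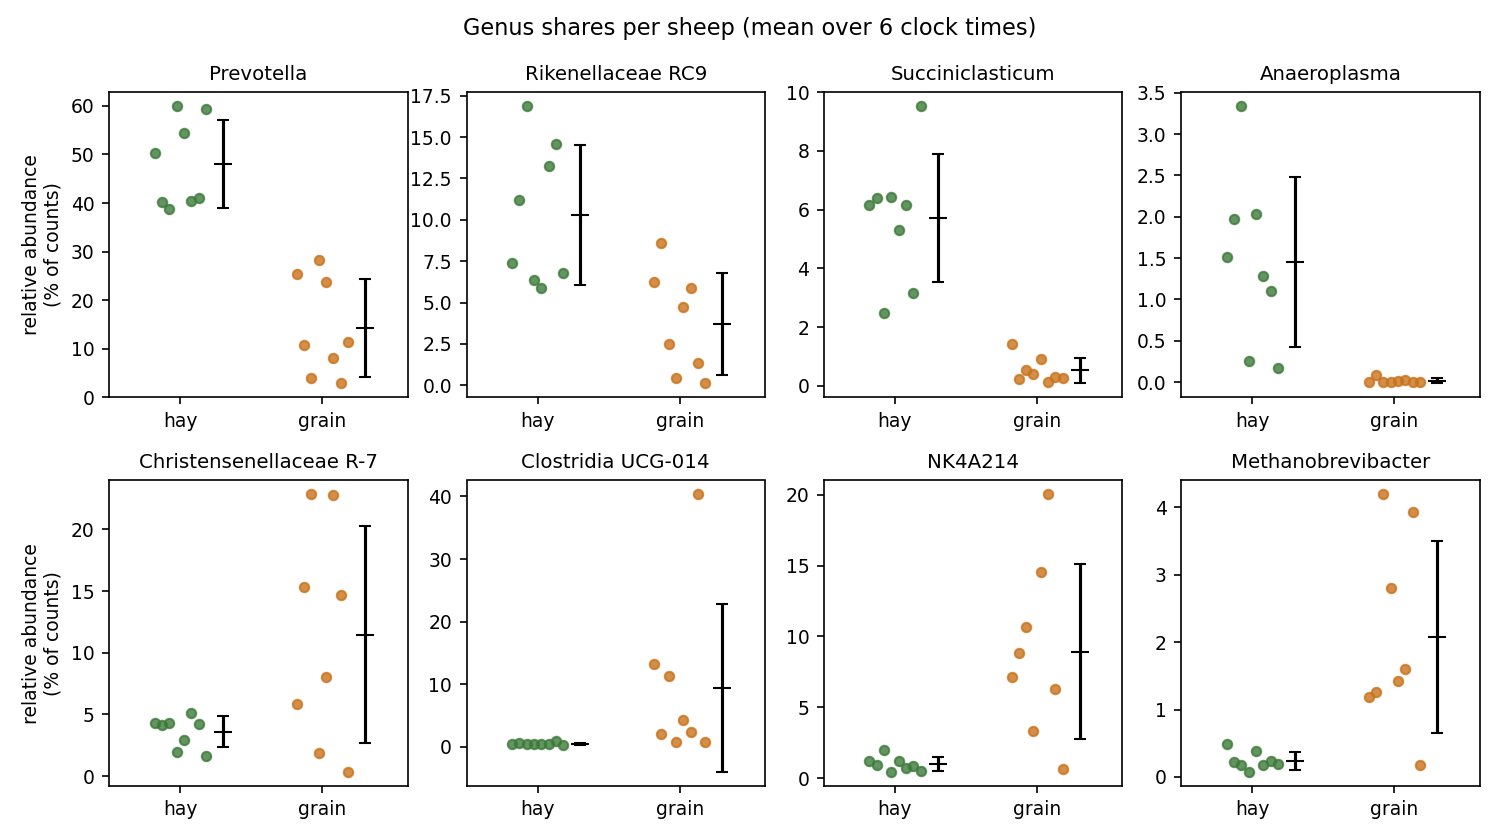
Relative abundance of 8 genera in each sheep (points, mean over the 6 clock times) by diet, with the mean and SD of the 8 sheep beside them. Prevotella and Succiniclasticum lay lower in all 8 grain-fed sheep than in every hay-fed sheep, while the genera of the lower panels spread widely among grain-fed sheep; the fall of Prevotella is not called under DESeq2 or centred log-ratio scaling, or without some single sheep.

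Several genera were close to a grain-only state. Bifidobacterium made up 7.47% ± 13.3 on grain and 0.00588% on hay, where 1 of 8 sheep held it (adjusted p = 0.00791; 0.0781 with sheep pairs joined). Pseudoscardovia, of the same family, made up 2.40% ± 5.44 on grain and was listed at 0 in all hay-fed sheep (adjusted p = 0.00503); grain sheep 8 held 15.5% of it, and the mean without this sheep was 0.53%. Without that sheep Bifidobacterium stood at 3.87%, and without grain sheep 4 Olsenella stood at 1.32%. Olsenella made up 2.75% ± 4.48 against 0.00338% (adjusted p = 0.00501; 0.0586 with sheep pairs joined). Streptococcus, the classic fast lactate former of the rumen, made up 1.42% ± 1.5 against 0.00256% and was found in 8 grain-fed and 2 hay-fed sheep (adjusted p = 9.93e-05). Flexilinea, the Chloroflexi genus behind the rise of its phylum, made up 1.62% ± 1.35 against 0.0177% (adjusted p = 1.67e-05). Howardella, a ureolytic genus, made up 0.170% ± 0.0984 against 0.00103% (adjusted p = 0.00117). Methanobrevibacter made up 2.07% ± 1.42 against 0.242% ± 0.132 (log2 fold change 3.23 ± 0.71, adjusted p = 0.000626), with 7 of 8 grain-fed sheep above every hay-fed sheep. Folds are left out for genera that were listed at or near 0 in a diet.

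Among the genera that fell on grain was the most abundant one of hay-fed sheep. Prevotella fell to 14.3% ± 10.1 from 48.1% ± 9.00, and all 8 grain-fed sheep lay below every hay-fed sheep (log2 fold change -1.72 ± 0.49, adjusted p = 0.00503). This call depends on the scaling: it was lost under DESeq2 (-0.57, adjusted p = 0.443), on centred log-ratios (-0.91, 0.288), with sheep pairs joined (0.0907) and without the 6 libraries that resembled another sheep (-1.11, 0.119), over a range from 7.53e-07 to 0.443. It was also lost when any 1 of grain sheep 2, 3, 5 and 7 and hay sheep 4 and 5 was left out (adjusted p up to 0.203). These scalings moved the median log2 fold change of all genera by 0.44 and 0.51 from its value of -0.67, less than they moved Prevotella, and the cause of the rest was not tested. Rikenellaceae RC9 gut group fell to 3.73% ± 3.08 from 10.3% ± 4.25 (log2 fold change -1.47 ± 0.59, adjusted p = 0.0332; 0.0631 with DESeq2, 0.0594 on centred log-ratios, 0.0542 without the 6 libraries and 0.154 with sheep pairs joined). Succiniclasticum, which turns succinate into propionate, fell to 0.528% ± 0.437 from 5.70% ± 2.18 in all 8 sheep (log2 fold change -3.43 ± 0.64, adjusted p = 0.000124), and this call held under each alternative (adjusted p from 4.01e-06 to 0.00839). F082 stood at 4.33% ± 3.66 and 4.39% ± 1.94 and was not called (adjusted p = 0.965).

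Less abundant groups nearly left the grain-fed rumen. Fibrobacter, a specialised cellulose degrader, made up 0.00699% on grain against 0.218% ± 0.210 on hay (adjusted p = 0.00905; 0.0781 with sheep pairs joined). Anaeroplasma, a wall-less bacterium, fell to 0.0167% from 1.46% ± 1.03 (adjusted p = 0.000482), Bacteroidales BS11 gut group to 0.00503% from 0.767% ± 0.498 (0.000128), and DEV114, a Verrucomicrobiota genus, to 0.000285% from 0.729% ± 0.345 (1.67e-05). Bacteroidales UCG-001, Papillibacter, Prevotellaceae Ga6A1 group, probable genus 10 and PeH15 fell in the same way, each with all 8 grain-fed sheep below every hay-fed sheep and adjusted p from 0.00094 to 0.00582. Clostridia vadinBB60 group was listed at 0 in all grain-fed sheep and stood at 0.1% ± 0.15 on hay (adjusted p = 0.000128). UCG-004, of the Erysipelotrichales, and UCG-002, of the Oscillospiraceae, fell to 0.0340% from 0.479% (adjusted p = 0.0289) and to 0.0261% from 0.372% (0.0327), and lost their calls with sheep pairs joined (0.117 for each). Several of these low grain means rest on 1 sheep: without grain sheep 2, Fibrobacter stood at 0.00185%, Anaeroplasma at 0.00627%, UCG-004 at 0.0146% and UCG-002 at 0.0106%, and without grain sheep 1, BS11 gut group stood at 0.00274% and DEV114 at 0. On hay, Clostridia vadinBB60 group stood at 0.0514% without sheep 7. Of the 24 genera with the largest rises and falls, 18 were also past the threshold with sheep pairs joined.

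Genera were also summed in lists named after functions known from the rumen, fixed before the data were examined. No function was measured, so a list's share is only the summed share of its genera. Lactate producers made up 12.0% ± 16.8 of counts on grain and 0.0118% ± 0.0259 on hay (exact permutation, adjusted p = 0.000725), and all 8 grain-fed sheep lay above every hay-fed sheep. Sheep 4 and 8 carried most of this difference, which was 12.0 percentage points with them and 3.00 without them in both diets (exact permutation, adjusted p = 0.00505). The list's measured members were Bifidobacterium, Olsenella, Streptococcus, Lactobacillus and Kandleria, the last named here to complete the list. Lactobacillus made up 0.371% ± 0.425 on grain in 7 sheep, was listed at 0 on hay, and was not tested after the filter. Lactate users rose to 4.14% ± 3.15 from 1.26% ± 0.611 (exact permutation, adjusted p = 0.00544). Among them Selenomonas stood at 3.03% ± 3.32 against 1.12% ± 0.499 and was not called by edgeR (adjusted p = 0.101) but was by DESeq2 (0.00203; range over alternatives 0.000918 to 0.250). In edgeR it was called without any 1 of grain sheep 3, 4, 7 and 8, the lowest adjusted p being 0.0309, and its grain mean without sheep 2 was 1.96%. Megasphaera, listed at 0 on hay, was found in 4 of 8 grain-fed sheep, and grain sheep 8 held 5.30% of it. Anaerovibrio was not called (adjusted p = 0.355; 0.0474 without grain sheep 7), and Coprococcus made up 0.0108% on grain and 0.000915% on hay. Without Selenomonas, the list's rise of 0.969 percentage points was not past the threshold (exact permutation, adjusted p = 0.346).

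Starch and sugar users fell to 27.8% ± 16.6 from 53.6% ± 9.64 (exact permutation, adjusted p = 0.00544), and this fall rested on Prevotella. Without it, the list rose by 7.96 percentage points (exact permutation, adjusted p = 0.0252). Prevotellaceae UCG-003 fell to 0.695% ± 0.686 from 3.48% ± 1.44 (adjusted p = 0.0208; 0.0511 with sheep pairs joined, over a range from 0.00569 to 0.0687). Fibre degraders stood at 4.81% ± 3.22 against 2.03% ± 1.04 and were not past the threshold (exact permutation, adjusted p = 0.0554); without sheep 4 and 8 the difference was 3.86 percentage points and past it (exact permutation, adjusted p = 0.00505). In it, Ruminococcus rose, Fibrobacter fell, and Butyrivibrio (adjusted p = 0.389) and Pseudobutyrivibrio (0.744) were not called by edgeR. Butyrivibrio was called higher on grain by DESeq2 (0.0359), on centred log-ratios (adjusted p = 0.0419) and without sheep 4 and 8 (0.0136), over a range up to 0.757, and Pseudobutyrivibrio on centred log-ratios (0.0459), over a range up to 0.916. Uncultured groups of fibre diets stood at 30.1% ± 19.6 against 21.2% ± 7.16 (exact permutation, adjusted p = 0.250): Christensenellaceae R-7 group and NK4A214 group rose, and Rikenellaceae RC9 gut group fell. Succinate and propionate formers stood at 3.59% ± 3.30 against 6.84% ± 2.29 (exact permutation, adjusted p = 0.0555), a fall carried by Succiniclasticum; as a log2 ratio to all other counts the fall of -1.64 was past the threshold (exact permutation, adjusted p = 0.016). Without it, the list stood 1.92 percentage points higher on grain (exact permutation, adjusted p = 0.125). In this list, Succinivibrio was listed at 0 on grain and Schwartzia made up 0.0268% on grain. The pectin and treponeme list, mostly Lachnospiraceae, rose to 7.31% ± 2.68 from 4.57% ± 1.55 (exact permutation, adjusted p = 0.0333). Its call was lost without sheep 4 and 8 (exact permutation, adjusted p = 0.240), without its most abundant member (0.225) and without the 6 libraries that resembled another sheep (0.0528). In it, unclassified Lachnospiraceae (adjusted p = 0.0533) and Lachnospiraceae XPB1014 group (0.0511) lay just above the threshold of 0.05; the first passed without any 1 of grain sheep 1 to 7, with DESeq2 (5.21e-05), on centred log-ratios (0.00556) and without sheep 4 and 8 (0.00922), and the other without grain sheep 8 (0.0209), with library totals (0.0465), without sheep 4 and 8 (0.0366) and with the place in the numbering as a block (adjusted p = 0.0142).

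The list of methanogens held Methanobrevibacter alone and rose (exact permutation, adjusted p = 0.00381). Taken as the log2 ratio to all other counts, its rise of 2.38 was not past the threshold (exact permutation, adjusted p = 0.136). Methanomassiliicoccus, a methanogen genus outside the list, made up 0.0163% on hay and was listed at 0 on grain. Sulfate reducers and acetogens fell to 0.122% ± 0.0722 from 0.365% ± 0.252 (exact permutation, adjusted p = 0.0375), which joins a lower share of Desulfovibrio (0.0626% against 0.365%; edgeR adjusted p = 0.0781, but 0.0265 with DESeq2, 0.0135 on centred log-ratios, 0.023 without sheep 4 and 8 and 0.0424 with the place in the numbering as a block) to Acetitomaculum, which was listed at 0 on hay and made up 0.0593% on grain, so that the list without Desulfovibrio rose (exact permutation, adjusted p = 0.021). The call of the list was lost without the 6 libraries that resembled another sheep (exact permutation, adjusted p = 0.0536). Genera known from reagents and the environment (Sphingomonas, Bradyrhizobium and Stenotrophomonas) made up 0.0562% ± 0.0283 on grain and 0.00251% ± 0.00401 on hay (exact permutation, adjusted p = 0.000725). All 8 grain-fed sheep lay above every hay-fed sheep in this list. A difference between the diets in how samples were handled was not tested and stays open. Of the lists with 1 measured genus, the wall-attached list (Howardella) rose (exact permutation, adjusted p = 0.000725), and the mouth list (Porphyromonas, 0.215), the hindgut list (Monoglobus, 0.215) and the plant organelle list (0.136) were not past the threshold. The last held only Gastranaerophilales, a gut lineage of the Cyanobacteria and not a plant organelle. In total 8 of 14 lists passed, and 0 did with sheep pairs joined, where 5 lists had the smallest exact p that 4 against 4 units can give, 0.0286, and an adjusted p of 0.08. Starch and sugar users then had an adjusted p of 0.171, and the pectin and treponeme list and sulfate reducers and acetogens 0.182 each (exact permutation). Counted over single genera, adjusting over the list alone changed the count in 1 list: of the pectin and treponeme list's 16 tested members, 2 were higher and 3 lower over all genera, and 2 higher and 2 lower adjusted over the list alone.

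Below the genus, features of 1 genus moved in opposite directions. Among 254 features tested with edgeR, 81 differed between diets, 32 higher and 49 lower on grain. Scaling by library totals gave 24 higher and 60 lower. Without the low-count filter, more features were called higher than lower on grain. The most abundant features higher on grain were a Bifidobacterium feature with 6.81% ± 12.0, a Clostridia UCG-014 feature with 5.87% ± 13.4 and a Prevotella feature with 2.80% ± 4.68 that was listed at 0 in all hay-fed sheep (adjusted p = 0.00687, 0.00312 and 0.000685). The most abundant features lower on grain were a pair of Prevotella features, which fell to 0.118% from 4.31% ± 2.13 (adjusted p = 0.0266) and to 0.0257% from 3.63% ± 2.84 (0.00508), and a Rikenellaceae RC9 gut group feature, which fell to 0.0295% from 2.66% ± 2.70 (0.0219). Prevotella thus held features that rose and features that fell. Each of the 3 features described as higher on grain had an SD above its mean, so few sheep carry these means. In grain sheep 7 the genus Clostridia UCG-014 made up 40.3% of counts, against 13.3% in the next sheep. Of all features, 427 were found in both diets, 291 on grain only and 228 on hay only, and the shared features held 73.7% of grain and 88.0% of hay counts.

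The diet difference was present at each clock time. Tested at single times with edgeR, 24, 18, 29, 20, 22 and 22 genera differed from T2 to T22, in the order of the clock. At all 6 times the same 6 genera were among them: Clostridia UCG-014, NK4A214 group, Lachnospiraceae NK3A20 group and unclassified Selenomonadaceae (1.46% ± 1.32 against 0.0850% ± 0.0681) were higher on grain, and Bacteroidales BS11 gut group and Prevotellaceae Ga6A1 group lower. The Selenomonadaceae entry was outside the rule for named genera and was chosen after its values were seen, to complete the count. The low-count filter was run anew at each time, so a genus left untested at any time could not be among these 6. DEV114, not tested at T6, and Flexilinea, not tested at T22, were called at each of the remaining times. At T14, 14 genera were higher and 6 lower on grain, against 10 and 9 with DESeq2 and 7 and 6 with library totals. At T2, 7 were higher and 17 lower, against 12 and 17 with DESeq2.

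Diversity within a sample was lower on grain at the level of features. Shannon diversity over features was 3.38 ± 0.673 on grain and 4.18 ± 0.493 on hay (difference of sheep means -0.802, exact permutation p = 0.0177, n = 8). A library held 126.5 ± 44.9 features on grain and 201.9 ± 33.9 on hay (exact permutation p = 0.00187). Over genera instead of features the Shannon difference turned to 0.227 (exact permutation p = 0.187). With sheep pairs joined, the exact permutation p was 0.114 for Shannon diversity and 0.0857 for features.

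**Figure D2:**
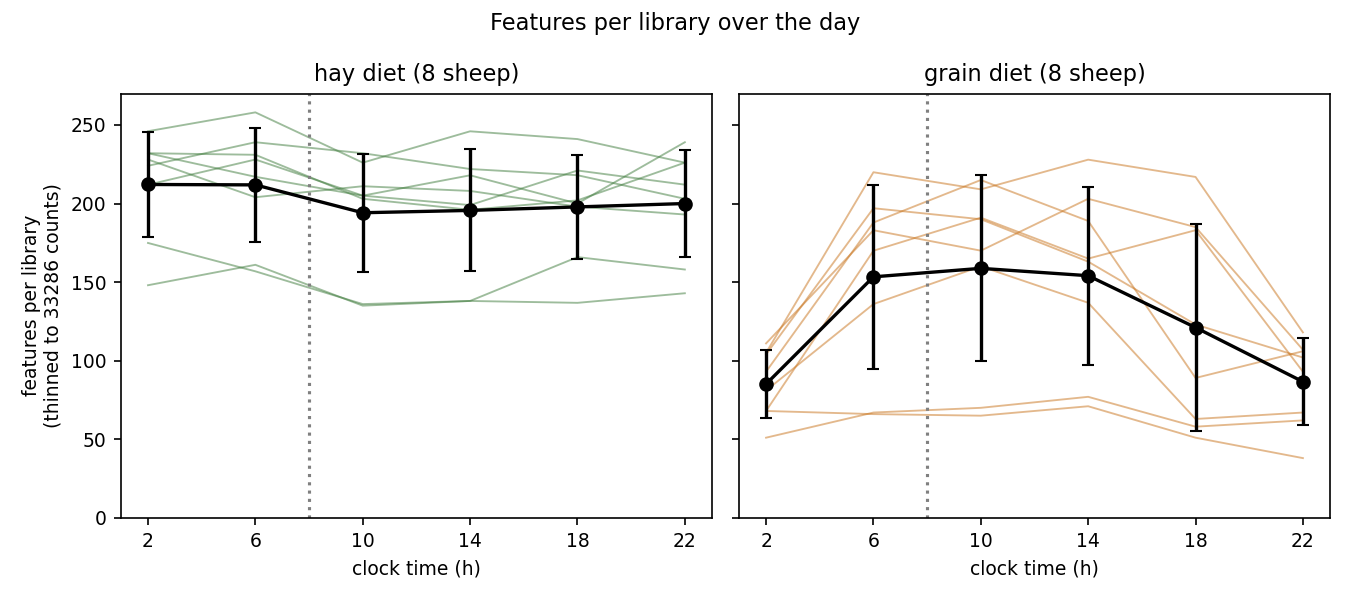
Features per library (counts thinned to the same total) against clock time in h for each of 8 sheep per diet (thin lines), with mean and SD (black) and the time of feeding (dotted). On grain the mean rose from 85.1 at T2 to 158.7 at T10 and fell back to 86.6 at T22, while on hay it stayed between 194.1 and 212.1, a smaller change that was also past the threshold (permutation within sheep, p = 0.0088).

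The question of the time comparison is how the community moves over the day on each diet. Samples came from 1 day, with feed given at 8 h, so a daily rhythm and the time since feeding were not separable. Clock time accounted for 8.40% of the variance of Bray-Curtis distances between grain libraries (times permuted within sheep, permutation p = 0.0001, the smallest these permutations can give) and for 8.21% between hay libraries (permutation p = 0.059). Sheep accounted for 68.7% and 55.6%. On hay the time call depends on the distance: Aitchison distance gave an R² of 0.107 and Jaccard distance of 0.114 (permutation p = 0.0001 for each), against 0.0821.

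On hay, of 75 genera tested with edgeR with the sheep as a block, 5 differed over the 6 times and 7 followed a cosine of 24 h. Prevotellaceae Ga6A1 group peaked at 21.8 h in the fit and went from 0.335% at T10 to 1.38% at T22, in 8 of 8 sheep (adjusted p = 1.64e-05). The genus entry named Ruminococcaceae peaked at 22.2 h and was higher at T2 (1.96%) than at T10 (0.515%) in 8 of 8 sheep (adjusted p = 2.3e-05). Ruminococcus peaked at 1.27 h, with 1.70% at T2 and 0.613% at T14, and again all 8 sheep showed this direction (adjusted p = 0.000277). Muribaculaceae peaked at 2.83 h, with 2.16% at T2 and 0.497% at T10 in 8 of 8 sheep (adjusted p = 0.00161). Christensenellaceae R-7 group ran the other way, with its peak at 10.8 h and a peak 1.39-fold over its trough (adjusted p = 0.0363; 0.0867 with sheep pairs joined, and lost without hay sheep 3, 4 or 5, at up to 0.368). Clostridia vadinBB60 group peaked at 6.1 h (adjusted p = 0.0346; 0.126 with sheep pairs joined, and lost without hay sheep 1, 3, 4, 5 or 8, at up to 0.152). Among phyla, whose courses were tested after the data were seen, Desulfobacterota (adjusted p = 0.0176), Chloroflexi (0.0234), Cyanobacteria (0.0298) and Euryarchaeota (0.0377) passed a permutation within sheep. These calls were not met by the tests of the genera that make up all or nearly all of each phylum: edgeR gave adjusted p of 0.41 over the times and 0.168 for the cosine for Desulfovibrio, 0.143 and 0.815 for Flexilinea, 0.143 and 0.152 for Gastranaerophilales, and 0.487 and 0.152 for Methanobrevibacter. The same permutation gave adjusted p of 0.0504 for the sulfate and plant organelle lists and 0.054 for methanogens; with sheep pairs joined these 3 passed (adjusted permutation p = 0.0196, 0.0346 and 0.0196). NK4A214 group (adjusted p = 0.0522; past it without hay sheep 2, 6 or 7) and Clostridia UCG-014 (0.0569; past it without hay sheep 8) were not past the threshold, nor was Prevotella on hay (adjusted p = 0.682). Some of these means rest on 1 sheep: Muribaculaceae at T2 was 1.30% without hay sheep 3, and at T10 Ga6A1 group was 0.199% without hay sheep 5 and Ruminococcaceae 0.320% without hay sheep 6. The counts depend on single sheep and times: without hay sheep 2 the time test gave 3 genera and without hay sheep 6 it gave 10, while the cosine gave 11 without hay sheep 6. Without T2 the time test gave 2 genera, and without T18 the cosine gave 4.

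On grain, Prevotella was most abundant from T6 to T14, around feeding, and Firmicutes receded. Prevotella made up 8.68% at T2, 15.7% at T6, 20.3% at T10, 23.3% at T14, 11.3% at T18 and 6.44% at T22, with a fitted peak at 11.3 h that was 7.53-fold over the trough (edgeR, adjusted p = 4.04e-06). All 8 sheep held more of it at T14 than at T22; the mean at T18 was 5.65% without grain sheep 4 and that at T22 was 4.08% without grain sheep 1. Firmicutes fell from 66.7% at T2 to 40.1% at T14 and returned to 69.6% at T22 (permutation within sheep, adjusted p = 0.0024), and Bacteroidota rose from 16.4% to 39.0% and fell to 12.9% (adjusted p = 0.0084 by the same permutation). Of 75 genera tested, 13 differed over the times and 15 followed a cosine of 24 h. Among the 15 were genera of low share on grain, such as Anaeroplasma, UCG-004, UCG-010 and Prevotellaceae Ga6A1 group. All of these were listed at 0 at T2. At its highest mean, Anaeroplasma was found in 3 of 8 sheep and each of the others in 4, so these courses rest on few counts. Olsenella stood at 1.25% at T2, 2.60% at T6, 7.90% ± 14.3 at T10 and 2.59% at T14 and 2.16% at T18, and was listed at 0 in all sheep at T22 (adjusted p = 0.0211; 0.111 with sheep pairs joined, where the test over 6 times kept its call with 0.0165). Without grain sheep 4 it stood at 0.138% at T2 and 3.27% at T10. Unclassified Atopobiaceae, of the same family, ran against it, listed at 0 at T6 and at 2.56% ± 6.30 at T22 with its peak at 22.6 h (adjusted p = 1.08e-05; at most 0.00048 with any 1 sheep left out). Without grain sheep 8 its mean at T22 was 0.332%. The fitted peak of Pseudoscardovia was at 13.7 h (adjusted p = 0.000801). Its mean share did not follow this peak and was highest at T18, where 4 of 8 sheep held it. The mean over T6, T10 and T14 (1.62%) was lower than over the other times (3.19%), although 5 of 8 sheep ran the other way. Lactobacillus had its fitted peak at 11.7 h (adjusted p = 0.0118), with 1.16% at T14 and 0.534% there without grain sheep 6. Prevotellaceae YAB2003 group had it at 10.9 h (adjusted p = 0.0113) and Shuttleworthia at 10.4 h (0.0398). Prevotellaceae YAB2003 group was found in 3 of 8 sheep at T6, its highest mean, and in 1 of 8 at T22, its lowest. With sheep pairs joined, the cosines of Pseudoscardovia (adjusted p = 0.13), Prevotellaceae YAB2003 group (0.111) and Shuttleworthia (0.283) were not past the threshold. Shuttleworthia's was also lost without grain sheep 5, 6 or 7 (up to 0.112). Spirochaetota, a phylum of low share on grain, passed the permutation within sheep (adjusted p = 0.0377), while Treponema, its genus there, did not pass edgeR (adjusted p = 0.109 over the times and 0.125 for the cosine). The mean of NK4A214 group over T6, T10 and T14 (5.86%) was lower than its mean over the other times (12.0%) in 8 of 8 sheep, but its fit was not past the threshold (adjusted p = 0.0677). These calls were sensitive to the model: DESeq2 gave 4 genera over the times and 4 with a cosine. Without grain sheep 2 the time test gave 6 genera, and without T2, T10 or T14 it gave 7 each; the cosine gave 6 genera without T2 or T10 and 7 without T22.

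**Figure D3:**
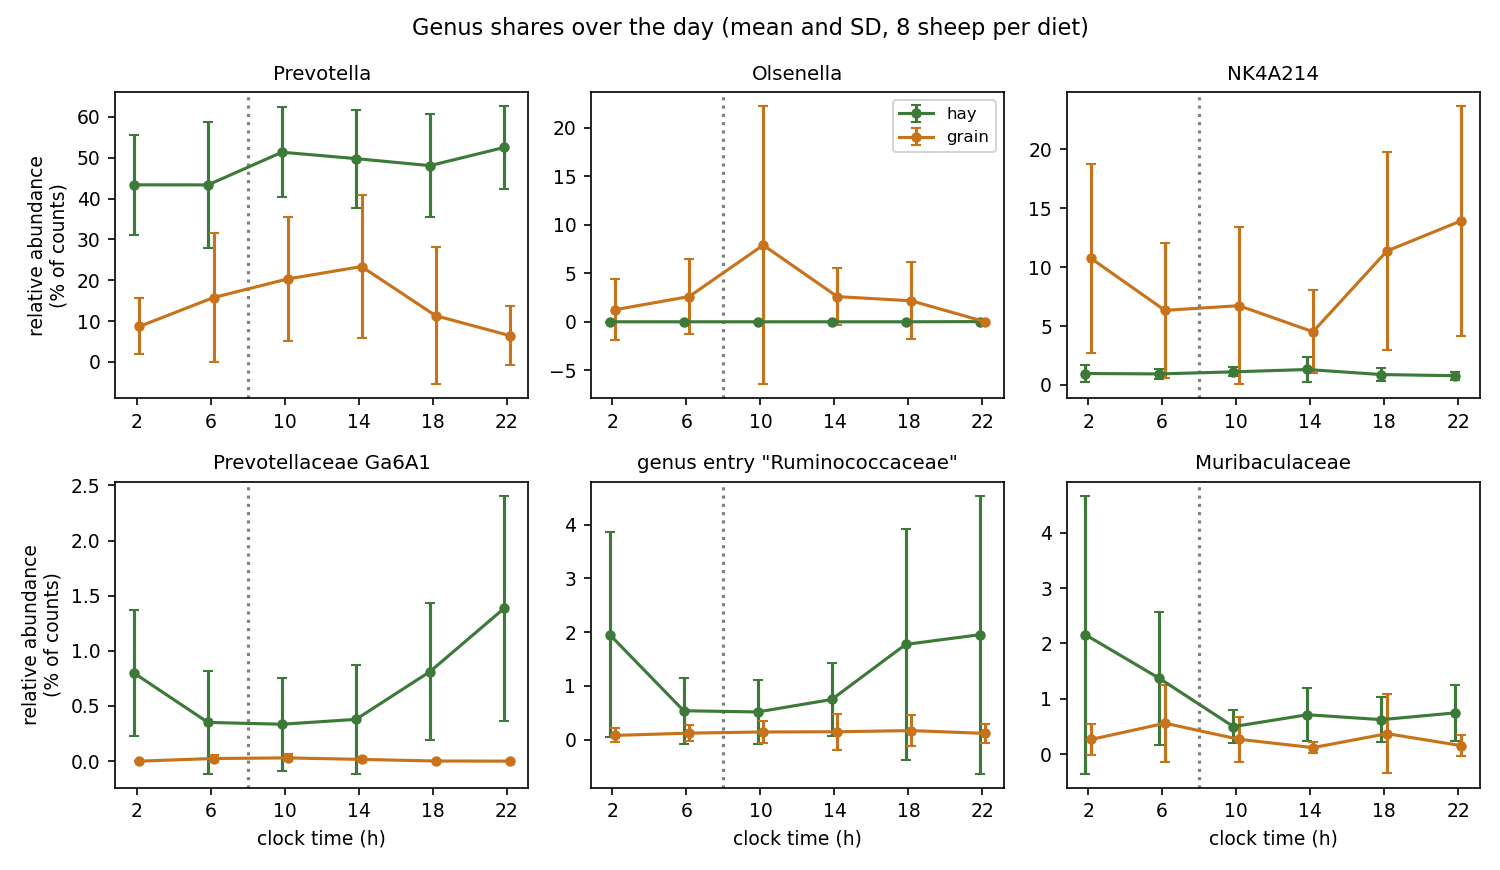
Relative abundance of 6 genus entries against clock time in h on hay and on grain (mean and SD of 8 sheep, dotted line at feeding). Prevotella on grain rose from 8.68% at T2 to 23.3% at T14, and on hay Prevotellaceae Ga6A1 group rose to 1.38% at T22.

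Among the lists, starch and sugar users on grain changed over the day, from 21.7% at T2 to 39.6% at T14 and 15.0% at T22 (permutation within sheep, adjusted p = 0.00432). It was the only 1 of 27 combinations of list and diet past the threshold; lactate producers on grain, which stood at 18.5% at T10 (10.7% without sheep 4) and 4.35% at T22 (1.80% without sheep 8), had an adjusted permutation p of 0.054. With sheep pairs joined, 5 combinations passed, and without the 6 libraries the pectin and treponeme list on grain did too (adjusted permutation p = 0.0378). A change of Shannon diversity over the times was not past the threshold on grain (permutation p = 0.34) or on hay (0.055). It was on grain without sheep 4 and 8 (permutation p = 0.00092), and on hay with sheep pairs joined (0.013), without sheep 4 and 8 (0.016) and without the 6 libraries that resembled another sheep (0.032). The number of features, compared over the times only after the data were seen, rose and fell on grain: 85.1 ± 21.6 at T2, 153.3 ± 58.6 at T6, 158.7 ± 59.2 at T10, 154.1 ± 56.6 at T14, 121.1 ± 65.9 at T18 and 86.6 ± 27.8 at T22 (permutation within sheep, p = 1e-05, the smallest these permutations can give). On hay it fell from 212.1 ± 33.4 at T2 to 194.1 ± 37.7 at T10 (permutation within sheep, p = 0.0088).

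Whether the course over the day differs between diets was tested directly. Of 104 genera tested with edgeR, 25 had different courses over the 6 times and 26 a different cosine of 24 h. The 104 include genera listed at 0 in all libraries of 1 diet, such as Pseudoscardovia and unclassified Atopobiaceae on hay. These have no course on that diet to compare, so for them the test could not decide. Prevotella, which moved on grain, had another course on hay (adjusted p = 7.63e-06). Prevotellaceae Ga6A1 group, with its night peak on hay, was found on grain in 4 of 8 sheep at T10 and listed at 0 at T2 (adjusted p = 5.53e-07). UCG-010 (adjusted p = 5.87e-07), probable genus 10 (7.17e-06), UCG-004 (1.96e-05), Anaeroplasma (2.03e-05), Bacteroidales BS11 gut group (5.48e-05) and Papillibacter (5.86e-05) were likewise genera of hay-fed sheep that were listed at 0 on grain at T2 or T6. Their time courses on grain thus rest on few counts. On centred log-ratios, 13 and 16 genera differed. The number of features also had different courses on the diets (exact permutation of sheep between diets, p = 0.000311).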

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

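Tests of the number of features over the day and of its depth, and the counts of other splits of the samples, were chosen only after the result was seen; the test without 6 libraries was set down before its result.

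Dixon's criterion was applied to 180 groups of 8 values, of which chance marks about 1 in 20; it marked 42, more than chance gives, in groups whose shares are skewed and often at 0. On grain, sheep 2 stood above the others for Anaeroplasma (0.0896%), Bacteroidales UCG-001 (0.0534%), Fibrobacter (0.0429%), Selenomonas (10.5%), UCG-002 (0.134%), UCG-004 (0.170%), probable genus 10 (0.0219%) and the succinate and propionate formers (10.7%). Several of these are genera of the hay diet. Grain sheep 3 stood apart for Gastranaerophilales and with it the plant organelle list (0.0943% each), for Porphyromonas and with it the mouth list (0.00358% each), and for Lachnospiraceae XPB1014 group (0.935%). Grain sheep 1 stood apart for Bacteroidales BS11 gut group (0.0211%) and DEV114 (0.00228%), and grain sheep 5 for Monoglobus and with it the hindgut list (0.0911% each). Grain sheep 7 held 40.3% of Clostridia UCG-014, against 13.3% in the next sheep. The partner sheep 4 and 8 of the grain diet stood apart for genera of the Actinobacteriota, sheep 4 for Olsenella (12.8%) and sheep 8 for Pseudoscardovia (15.5%) and unclassified Atopobiaceae (5.03%). Sheep 4 did so also for Prevotellaceae YAB2003 group (1.56%) and sheep 8 for Megasphaera (5.30%).

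On hay, sheep 8 was the only sheep with Bifidobacterium (0.0471%) and Olsenella (0.0271%), and so stood apart for Actinobacteriota and for lactate producers (0.0741% each); these counts lie in its T22 library. Its T2 library had the lowest total (33286 counts) and its T10 library a low Shannon diversity (3.07). Hay sheep 2 stood apart for Gastranaerophilales and with it the plant organelle list (1.00% each), for Sphingomonas (0.00688%) and for the reagent list (0.0115%). Hay sheep 6 was the only one with Howardella, the sole member of the wall-attached list (0.00822% each). Hay sheep 1 stood apart for Coprococcus (0.00732%) and PeH15 (0.415%), sheep 3 for Muribaculaceae (2.31%), sheep 5 for Prevotellaceae YAB2003 group (1.02%) and Schwartzia (0.00128%), and sheep 7 for Clostridia vadinBB60 group (0.441%) and Streptococcus (0.0170%).

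Courses over the day that differed between diets, by edgeR's test of the interaction, are those of Prevotellaceae Ga6A1 group (adjusted p = 5.53e-07), UCG-010 (5.87e-07), probable genus 10 (7.17e-06), Prevotella (7.63e-06), UCG-004 (1.96e-05), Anaeroplasma (2.03e-05), Bacteroidales BS11 gut group (5.48e-05), Papillibacter (5.86e-05), Olsenella (0.00174), Prevotellaceae YAB2003 group (0.0365) and the genus entry Ruminococcaceae (0.0365). With sheep pairs joined, the last 2 were not past the threshold (adjusted p = 0.221 and 0.17). On hay, Olsenella was found only in the T22 library of sheep 8, so its course there rests on 1 library. The number of features per library differed too (exact permutation p = 0.000311).

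The number of features on grain rose from 85.1 at T2 to 153.3 at T6 and fell to 86.6 at T22, and in all 8 sheep the mean over T6, T10 and T14 lay above the mean over T2, T18 and T22. Depth and dominance do not account for all of it: with each library thinned to 1000 counts the change was smaller, from 74.0 at T2 to 112.0 at T10 (F of 9.13 against 12.96, permutation p of 1e-05, the smallest these permutations can give). With the 3 most abundant features of each library left out first, the means at 1000 counts were 75.8 and 122.6 (F of 13.78), and without the 6 libraries that resembled another sheep F was 13.74. The rise was present at T6, before the feed of the day. Feeding, a daily rhythm and the order in which samples were handled stay open, since each clock time was sampled on 1 day only.

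Counts of called genera were set against those of other splits (100 each, the real one included, which gave the highest count in each). These splits treat all sheep as independent, which the sheep pairs put in doubt. They argue against chance as the source only if the sheep are independent. Between diets, 46 genera were called against at most 13 in another split of the 16 sheep, and 81 features against at most 6. At the single times, in the order of the clock, the real counts were 24, 18, 29, 20, 22 and 22, against at most 1, 3, 6, 1, 2 and 2. With times permuted within sheep, the time test gave 5 genera on hay and 13 on grain against at most 1 in either diet, and the 24 h cosine gave 7 against 2 on hay and 15 against 1 on grain. The interaction gave 25 genera against at most 15 over the times, and 26 against at most 13 for the cosine. Among the 35 splits that keep sheep pairs together, the real split gave 46 genera and the highest other 5. The counts of features, of single times, over the day and of the interaction were not tested with sheep pairs kept together.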

How the results depend on the processing

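Joining sheep pairs, leaving out 6 libraries that resembled another sheep, leaving out sheep 4 and 8 and blocking by the place in the numbering were chosen after the data were seen; the other alternatives were planned. Of 311 alternatives for counts and summary values, 256 kept their direction and side of the threshold and, for counts, stayed within 1.5 times the reported one. Of those for single phyla and lists 341 did, with 31 losing and 10 gaining a call and 4 turning. Of 300 for the fold changes of named genera (3 scalings and the alternatives chosen after the data were seen) 245 did, with 27 losing and 20 gaining a call and 8 turning; joined pairs alone ended 14 calls. The counts of genera and features called between diets stayed within that bound under DESeq2, also at single times, and over all times when any sheep was left out (48 to 54 genera, 91 to 119 features). Where no cause is given below, the cause was not tested. Without the low-count filter more genera are tested, and 86 of 120 genera (46 higher, 40 lower) and 607 of 946 features (337 higher, 270 lower) were called between diets, and 76, 71, 70, 72, 78 and 75 genera at the single times from T2 on. Of the 49 genera that the filter leaves out, 27 are listed at 0 on hay and 9 on grain. With library totals, 13 genera were called at T14. With sheep pairs joined, which leaves 4 units per diet, 38 genera were called, 24 of them shared with the 46, and 18, 9 and 34 at T10, T14 and T22. The Shannon difference stayed at -0.802 and that of features at -75.4, but neither was past the threshold, 7 phyla and 0 lists were called between diets, and 5 combinations of list and diet changed over time (2 without the 6 libraries). The 24 h cosine then gave 4 genera on hay and 7 on grain, and the time test 5 on grain. On hay, the time test gave 3 genera on centred log-ratios, 2 without T2 and 10 without sheep 4 and 8, and 3 to 10 with 1 sheep left out. The cosine on hay gave 11 with DESeq2, 4 without T18 and 5 to 11 with 1 sheep left out. On grain, the time test gave 7 genera on centred log-ratios and without T2, T10 or T14, 4 with DESeq2 and 6 to 18 with 1 sheep left out. The cosine on grain gave 9 on centred log-ratios, 4 with DESeq2, 6 without T2 or T10 and 7 without T22. Without the sheep as a replicate block, edgeR gave 0 genera for the time test on hay (5 at an unadjusted p under 0.05, and 11 on grain adjusted), and 2 and 8 for the cosine on hay and grain. On centred log-ratios, the interaction gave 13 genera over the times and 16 for the cosine. The Shannon difference turned to 0.227 over genera. The F of Shannon diversity over time on hay rose to 3.04 with sheep pairs joined, 2.55 without the 6 libraries and 3.41 without sheep 4 and 8, and to 5.87 on grain without sheep 4 and 8, each past the threshold. For hay, the R² of time passed with Aitchison (0.107) and Jaccard (0.114) distance, over features (0.0596) and with sheep pairs joined (0.116). Without its most abundant member, 4 lists were called; the starch list turned to 7.96, the succinate list to 1.92 and the sulfate list to 0.0593 percentage points, since 1 genus made up each fall. As a log2 ratio, the uncultured fibre list turned to -0.18. F082, not called, turned to 0.33 with DESeq2, 0.47 on centred log-ratios, 0.24 with pairs joined, 0.011 without the 6 libraries and 0.40 without sheep 4 and 8. Prevotellaceae YAB2003 group, not called, turned to -1.21 on centred log-ratios, -2.16 without sheep 4 and 8 and -3.32 with the place as a block. The sheep numbers are shared by different animals of the diets: the correlation of deviations of same-numbered sheep was 0.0289 to 0.142, with 3 of 8 above 0.1 and 4 of 8 best with their own number, so the single numbers do not meet the bound set for pairing the diets. The sheep pairs of the same place in the numbering did deviate together across diets (mean correlation 0.113, lowest 0.0674). With the sheep number as a block, 44 genera and 115 features were called, and with that place as a block 50 and 121. How depth bears on genera near 0 was not tested, and the table omits rare features.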

Other observations

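Chosen after the result was seen were the tests of the pairs against other pairings and between diets, the test without sheep 4 and 8 and that with the sets as a block; the tests of carry-over and of the counts without Prevotella were set down before their results.

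Sheep 1 and 5, 2 and 6, 3 and 7, and 4 and 8 resembled each other in both diets, a pattern that no label names. Among the 105 ways to pair 8 sheep, 1 had a mean distance as low as this pairing in each diet, the pairing itself, and 8 of 8 sheep in each diet were nearest to their partner, so chance numbering is an unlikely source. Material carried over between libraries of the same clock time is argued against as the whole source: partners' libraries of different times were nearer than libraries of other sheep at the same time in all 8 pairs, though partners' libraries of the same time were nearer still in 6 of 8 pairs, so a small share of it stays open. Across diets, hay and grain pairs of the same place in the numbering deviated from their diet's mean together (mean correlation 0.113, against -0.0374 for others), and 1 of 24 assignments was as high, the real one. This is consistent with a grouping of sheep or of libraries in sets that both diets share, such as pens, origin or processing order, among which these data do not decide; no biological explanation was tested.

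The genera higher on grain might follow from the closed sum of shares, as the share of Prevotella was much lower on grain. With Prevotella left out of the counts, 19 of the 19 genera called higher were called higher again, and 17 of the other 26 called lower were called lower again. Without sheep 4 and 8 of both diets, 19 of 19 and 22 of 27 were called again. The sets of sheep each hold 2 sheep of either diet, and with these sets as a block 18 of 19 were called higher. Since each set holds both diets equally, such a block could hardly change a diet difference. The block test therefore cannot decide whether the sets bear on the rises. Sheep 4 and 8 do not account for the rises alone, while the closed sum stays open. Without Prevotella 9 of the falls were not called, in a fit that moved the rises upward. These lost calls alone do not show whether the falls depended on Prevotella. A response to the diet stays a hypothesis. Cell numbers were not analysed here, and other differences between the diet groups, such as housing or handling, were not tested.

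Of the 96 libraries, 75 were nearest to a library of the same sheep, 15 to the partner sheep and 6 to another sheep of the same diet (grain sheep 4 at T22, 5 at T22, 6 at T18 and 6 at T22, and hay sheep 4 at T10 and 8 at T2). 0 were nearest to the other diet. No library was found to be deposited a second time: the closest pair, hay sheep 7 at T2 and T22, differed by a chi-square of 30.7 per degree of freedom.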
